A study of Mus musculus with 44 samples.

How the data were processed

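RNA was measured in total homogenates of brain, liver and small intestine from C57BL/6J mice of about 2 months that had received vehicle or manganese (about 50 mg of hydrated manganese chloride per kg of body weight daily), per the labels. The 44 libraries came from 15 animals named by the number in each label. There were 7 vehicle animals (3 female, 4 male) and 8 manganese (Mn) animals (3 female, 5 male). Brain and liver had 7 vehicle and 8 Mn libraries each, and small intestine had 7 and 7, because Mn animal 2601 has no small intestine library here. Libraries were made per the labels' protocols with 3′ TagSeq, which reads the 3′ end of polyadenylated RNA, so that a count reflects transcripts with little dependence on transcript length.

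The values analysed were the raw read counts per gene that the authors deposited, 1 file per library. Per the submitters' processing notes the tools were FastQC 0.12.0, STAR 2.7.10b, HTSeq 0.2.0, R 4.2.2 and DESeq2 1.12.3, and the genome build was GRCm39. Whether TagSeq molecular identifiers were used to remove duplicate reads is not given in the sources used here, so that counts may hold duplicates and all intervals and tests rest on reads. Each file held 55416 genes, 92 spike-in entries (4 counts in all, over 3 of them) and 5 summary entries. Over the 44 libraries, reads assigned to genes made up 60.7% to 69.8% of the records, reads without a feature 1.84% to 4.14%, ambiguous reads 2.06% to 2.53% and multi-mapped reads 23.8% to 34.8%. The 2 remaining summary entries were at 0 in every library. The summary and spike-in entries were left out of library sizes and tests. Multi-mapped reads were not counted, so that values of near-identical gene families (Mup, Ugt2b, Cyp2c, Cyp2a, Sult and Serpina1 genes among those named) are uncertain. Gene symbols came from a GRCm38 annotation, matched by gene identifier: 52083 of the 55416 identifiers matched and 3333 did not. No coordinates are given, because that build is not the one the counts were made on.

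The total assigned to genes was 1796385 to 3798810 reads per library. At a depth in the middle of that range, 10 reads correspond to about 4 CPM (read counts scaled to a common library total), so that genes below that level carry a large counting error. TMM factors ranged from 0.942 to 1.07. No 2 libraries of a group were duplicates: the lowest chi-square per gene between libraries of a group was 1.47. The sex labels fitted the Y-linked genes, which summed to 133 to 226 CPM in libraries labelled male and 2.15 to 7.44 CPM in those labelled female.

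Within each tissue, Mn was compared with vehicle with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), TMM scaling, genes kept by filterByExpr (minimum count 10, minimum total 15), sex as a covariate and a Benjamini-Hochberg adjusted p below 0.05. All adjusted p-values below are from these edgeR fits unless another tool is named, and all tests are two-sided. Fold changes are log2, Mn over vehicle, with their standard errors (SE), and group values are mean CPM ± SD computed with TMM-scaled library sizes. The sex by treatment term was tested in each tissue, and the tissue by treatment contrasts were tested in 1 fit of all 44 libraries with sex nested in tissue. Shared calls between tissues were tested with Fisher's exact test. For 51 gene lists, camera (limma 3.58.1) was run with a preset inter-gene correlation of 0.01 on lists with at least 3 tested members, again with an estimated correlation, and with fry. The tests, covariates, lists, the rule for naming genes and most alternatives were fixed before the data were examined.

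The rule named, per tissue, up to 8 genes with the largest increase and up to 8 with the largest decrease among those with adjusted p below 0.05, a mean of at least 2 CPM and a symbol that is not a placeholder. It added the 6 genes with the smallest p, up to 4 members per list with adjusted p below 0.05 by smallest p, and in every case the tested kynurenine pathway genes and Slc30a10, Slc39a14, Slc39a8, Slc11a2, Slc40a1, Tfrc and Mt1. For each interaction it took up to 5 passing genes with the smallest p, or 3 if none passed. Any gene named outside the rule is said to be so. Some genes that the rule names are not reported here and were left out of the counts of named genes.

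The tissues came from the same animals, which the shared animal numbers in the labels identify, so the fit with the animal as a replicate block is given where it changed a call. The deviations of an animal's tissues from their group means, over 6716 genes, had a median correlation of 0.08 between brain and liver (range −0.18 to 0.40), 0.06 between brain and small intestine (−0.16 to 0.23) and 0.17 between liver and small intestine (0.01 to 0.36).

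After the counts had been examined, the share of each other tissue's RNA profile was estimated in each library. Markers were genes with at least 100 CPM in the source tissue, a lowest level in the target tissue of at most 0.5% of that, and a level in the remaining tissue of at most 10% of it. They numbered 217 for liver in brain, 197 for small intestine in brain, 478 for brain in liver, 309 for brain in small intestine, 181 for liver in small intestine and 170 for small intestine in liver. A share is the summed CPM of the markers in the library as a percentage of the sum of their median CPM in the source tissue, both on unscaled library sizes. It cannot tell tissue carried along at dissection from RNA or reads that crossed between samples later. Libraries with a share of at least 1% (of liver or small intestine in a brain library, of brain in a liver or small intestine library) were called doubted. Alternatives added at that stage left the doubted libraries out, used the shares as covariates, subtracted the predicted reads, or tested only genes whose mean CPM in the other tissues was at most 2 times that in the tissue tested. For the tissue contrasts the last of these kept only genes whose highest tissue mean was at most 2 times the lower mean of the tissues compared. A further added alternative took the difference between the tissues' own fits in place of the joint fit.

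Alternatives fixed at that earlier stage were DESeq2 1.42.0, limma-voom, RLE and library-size scaling, no and a stricter low-count filter (at least 1 CPM in 7 libraries), no sex covariate, 1 surrogate variable (sva 3.50.0), the animal number series (2572 to 2578 against 2600 to 2630) as a covariate or each series alone, each sex alone, and leaving out each animal in turn. Within each series, vehicle and Mn animals held separate runs of numbers. The series fits therefore cannot part treatment from animal number within a series.

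The edgeR fits of the tissues, the sex term and the tissue contrasts, and camera, were tested on simulated counts with known changes. DESeq2, limma-voom, fry, the exact test of shared calls, the share estimate and the subtraction of reads were not tested in this way. Genes changed 1.5, 2 and 4 fold were recovered at 56.1%, 81.3% and 100% in brain (13043 genes, 5.66% of calls false), at 57.1%, 93.8% and 96.5% in liver (10562 genes, 3.21% false) and at 48.4%, 92.3% and 100% in small intestine (11819 genes, 3.68% false). For the sex by treatment term, 4-fold differences were recovered at 80.0%, 83.1% and 86.2% in brain, liver and small intestine, and 1.5-fold differences at 9.09%, 9.09% and 4.48%. The 3 lists moved 1.3 fold in each tissue were all called by camera with the preset correlation, and 3, 3 and 2 of them with the estimated one. Of the lists not moved, 0 of 34, 1 of 38 and 0 of 36 were called. The simulated genes varied independently of one another. These counts of lists therefore do not show how camera, with either correlation, performs on genes that vary together. The joint fit assumes 1 dispersion per gene in all tissues. A first simulation gave genes filtered out of a tissue the highest dispersion there, and 21.6%, 24.9% and 28.9% of the joint fit's calls were then false (brain against liver, brain against small intestine, liver against small intestine; 15185 genes). The simulation was changed after that result was seen: with a dispersion from the trend for such genes, 4.44%, 3.85% and 4.05% of calls were false (14989 genes). The difference between the tissues' own fits, run on the first simulation, gave 2.24%, 5.48% and 1.56% false calls. Counts from the joint fit are therefore given beside those from the tissues' own fits.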

Results

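RNA of brain, liver and small intestine was profiled in 15 mice given vehicle or manganese (Mn) daily. The title of the series links raised brain Mn, the kynurenine pathway of tryptophan breakdown and motor disease. There were 7 vehicle animals and 8 Mn animals, each a separate mouse, and the animals are named by number below. Reads assigned to genes per library numbered 1907393 to 2787449 in vehicle brain, 1883082 to 3798810 in Mn brain, 1851623 to 2667301 in vehicle liver, 1796385 to 2856032 in Mn liver, 2177396 to 2945552 in vehicle small intestine and 2035736 to 3200867 in Mn small intestine. In each tissue Mn was compared with vehicle, the Mn effect was compared between the sexes, and the effects were then compared between tissues. In liver and in small intestine, vehicle and Mn libraries stood in separate runs of sample numbers. A batch that follows these numbers cannot be told apart from the treatment there.

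In brain, the organ the series title names, 72 genes rose and 2 fell with Mn among 12872 tested (adjusted p below 0.05), and 70 of the 72 had a mean level in liver or small intestine more than 2 times that in brain. Fabp1 (ENSMUSG00000054422.8), the fatty acid binding protein of liver and gut, rose from 1.78 ± 1.06 to 126 ± 55.4 CPM (SD, n = 7 and 8), a log2 change of 6.13 ± 0.59 (SE, adjusted p = 6.3e-05), and lay above every vehicle library in 7 of 8 Mn libraries. Apoa1, an apolipoprotein, rose from 8.12 ± 4.4 to 165 ± 82.3 CPM (4.33 ± 0.52, adjusted p = 0.000137). Cps1, the first enzyme of the urea cycle, rose by 5.47 ± 0.57 (adjusted p = 9.2e-05), the fibrinogen gene Fgb by 5.26 ± 0.58 (adjusted p = 0.000102) and the gut and bile antibody receptor Pigr by 6.05 ± 0.77 (adjusted p = 0.000202). The median log2 change of the 72 genes was 4.32.

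The brain libraries differed between the groups in their estimated share of liver and small intestine genes. The 7 vehicle libraries and that of Mn animal 2575 held 0.0836% to 0.309% of the liver profile and 0.1% to 0.194% of the small intestine profile. The other 7 Mn libraries were doubted. Those of the females 2576 and 2600 held 5.90% and 3.13% of the small intestine profile. Those of the males 2577, 2578, 2601, 2602 and 2603 held 3.91%, 4.0%, 2.61%, 2.41% and 2.45% of the liver profile. Leaving these 7 out keeps a single Mn brain library, which is assumed to vary like the vehicle libraries. By edgeR 0 genes were then called higher and 2 lower, with 0 shared with the 74 (1440 genes at an unadjusted p below 0.05). The 2 were Oxt (−3.58, adjusted p = 3.4e-05) and Avp (−4.01, adjusted p = 0.000111), hormones of the hypothalamus that the rule did not name. With edgeR, 0 genes were called when only genes not higher elsewhere were tested (649 at an unadjusted p below 0.05), when the shares were covariates (846) and when the predicted reads were subtracted (876). Subtraction took 51 of the 72 genes below the low-count filter and left 21 to be tested, so that its 0 does not bear on the 51. These fits were made with edgeR alone.

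**Figure D1:**
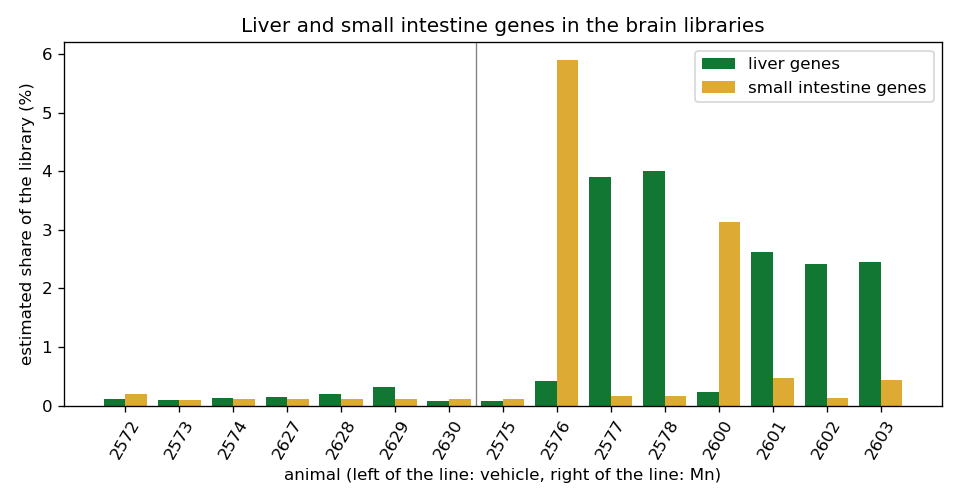
Estimated share (%) of liver genes (green bars) and small intestine genes (yellow bars) in each brain library, with vehicle animals left of the line and Mn animals right of it. The 7 vehicle libraries and Mn animal 2575 stay at or below 0.309% for liver genes, while the Mn animals 2576 and 2600 reach 5.90% and 3.13% for small intestine genes and the 5 male Mn animals reach 2.41% to 4.0% for liver genes.

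Of the genes that were not higher elsewhere, 2 rose and 2 fell in brain. Slc7a5, a transporter of large neutral amino acids that include tryptophan, rose from 41.6 ± 3.68 to 57.4 ± 8.99 CPM (0.44 ± 0.09, adjusted p = 0.0210; above every vehicle library in 7 of 8). Hspb1, a small heat shock protein, fell from 36.5 ± 8.11 to 20.8 ± 4.62 CPM (−0.82 ± 0.16, adjusted p = 0.0203; below every vehicle library in 7 of 8). Tmem107, a cilium protein, fell by 0.80 on the log2 scale (SE 0.17, adjusted p = 0.0349). Without 1 library the call of Hspb1 was lost (without Mn 2576, 2577, 2601 or 2603, adjusted p up to 0.0868), and Slc7a5 kept its call in 7 of 15 such fits (adjusted p up to 0.0813) and Tmem107 in 5 of 15 (up to 0.125). With the predicted reads subtracted, the changes stayed about as large, at 0.48 ± 0.09 for Slc7a5, −0.83 ± 0.16 for Hspb1 and −0.75 ± 0.17 for Tmem107 (adjusted p = 0.140, 0.224 and 0.271). Their calls ended there because fewer genes with a small p were left for the adjustment, which does not argue for reads of other tissues as their cause. With the shares as covariates the changes were 0.31 ± 0.12, −0.89 ± 0.33 and −0.58 ± 0.31 (adjusted p = 0.718, 0.718 and 0.754). With the doubted libraries left out they were 0.29 ± 0.18, −0.48 ± 0.32 and −0.24 ± 0.41, and none of these was called. Over all alternatives the adjusted p of Slc7a5 ran from 0.00246 to 1.0 and that of Hspb1 from 0.000511 to 1.0.

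By gene list, 26 of the 47 lists tested in brain were called with the preset correlation (22 up, 4 down) and 12 of these with the estimated one. Among 16 hepatocyte markers tested, 9 rose (12 adjusted over the list alone), and 15 of the 16 were higher elsewhere. Among 11 enterocyte markers 6 rose (10 adjusted over the list alone), and 11 were higher elsewhere. Both lists were called up (adjusted p = 0.00788 each with an estimated correlation). Of the 22 cholesterol synthesis genes, 22 had a positive change (median 0.26), 1 rose and 14 passed when adjusted over the list alone (adjusted p = 0.0160 with an estimated correlation), with 16 of the 22 higher elsewhere. Hmgcs1, an early enzyme of that pathway, rose from 160 ± 4.45 to 213 ± 33.8 CPM (0.40 ± 0.08, adjusted p = 0.0274). It kept its call in 5 of 15 fits that left out 1 animal (adjusted p up to 0.107), and was at 0.39 ± 0.08 with the predicted reads subtracted (adjusted p = 0.224) and 0.074 ± 0.12 with the shares as covariates. The manganese and divalent metal transport list was called up with 13 tested members, 0 of which passed over all genes and 3 over the list alone (adjusted p = 0.0454 with an estimated correlation), with 7 of them higher elsewhere. Its members Slc30a10, the Mn exporter (20.4 to 25.6 CPM; 0.34, adjusted p = 0.405), Slc39a14 (0.03, adjusted p = 0.989), Slc39a8 (0.36, adjusted p = 0.752), Slc11a2 (0.26, adjusted p = 0.444) and Slc40a1 (1.03, adjusted p = 0.239) did not pass. Without the doubted libraries, where a single Mn brain library is left, Slc40a1 was at −0.45, Slc39a8 at −0.28 and Slc30a10 at −0.055. With the predicted reads subtracted Slc40a1 was at −0.55 and Slc30a10 at −0.041. The direction given for Slc40a1 and Slc30a10 was thus not kept in these fits, and that of Slc39a8 was not kept in the first of them. Without the doubted libraries, with the preset correlation, the hepatocyte and enterocyte lists were not called (adjusted p = 0.239 and 0.387, both downward), nor was the metal transport list (adjusted p = 0.716). The cholesterol list was called up there (adjusted p = 0.00303), but that fit has a single Mn brain library and Hmgcs1 changed by −0.093 ± 0.12 in it.

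Other brain lists hold mostly genes that are not higher elsewhere. Of 16 cytosolic heat shock genes, 15 had a negative change (median −0.16), 1 fell and 4 fell when adjusted over the list alone (adjusted p = 0.106 with an estimated correlation). Of 20 oligodendrocyte and myelin markers, 18 had a positive change (median 0.14) and 3 passed when adjusted over the list alone (adjusted p = 0.182 with an estimated correlation). Hormone genes of pituitary and hypothalamus were negative for 13 of 14 (0 called, 4 adjusted over the list alone, adjusted p = 0.168 with an estimated correlation). The pituitary hormone Prl, chosen after its values were seen, was at 1282 ± 3263 CPM in vehicle and 24.2 ± 36.2 CPM in Mn brain (adjusted p = 0.124). Vehicle 2572 carried that mean with 8681 CPM, against 48.7 ± 36.1 CPM in the 6 other vehicle brains. Without it Prl was at −1.65 ± 0.71 (adjusted p = 0.511) and 12 of the 14 hormone genes were negative (median −0.35, adjusted p = 0.271 with an estimated correlation).

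The kynurenine pathway list held 15 genes, of which brain expressed 5 above the low-count filter. None of the 5 passed: Kyat3 (0.52 ± 0.24, adjusted p = 0.583), Gcdh (0.46 ± 0.13, adjusted p = 0.199), Kyat1 (0.09 ± 0.10, adjusted p = 0.923), Got2 (0.07 ± 0.07, adjusted p = 0.911) and Nadsyn1 (0.11 ± 0.28, adjusted p = 0.984). Together they were called up with the preset correlation (adjusted p = 0.00578), with 1 passing when adjusted over the list alone and 4 of the 5 higher elsewhere (adjusted p = 0.0801 with an estimated correlation). Without the doubted libraries Kyat1 and Nadsyn1 were negative (−0.36 and −1.25). Tdo2, which starts the pathway from tryptophan in liver, was at 0.490 ± 0.387 CPM in vehicle and 20.6 ± 15.1 CPM in Mn brain on unscaled library sizes, against a mean of 1435 CPM in liver. Without the filter its change was 5.16 (adjusted p = 2.2e-11), that of Kynu 3.18 (adjusted p = 0.000653), Haao 2.40 (adjusted p = 0.00720) and Aadat 2.05 (adjusted p = 0.0226). Kynu, Haao and Aadat averaged 0.187, 0.929 and 0.482 CPM in vehicle brain and 156, 510 and 107 CPM in liver. Kmo, the enzyme at the branch to quinolinic acid, was at 1.53 and 4.64 CPM (adjusted p = 0.0656), and Ido1 at 0.411 and 1.13 CPM (adjusted p = 0.671). The estimated liver share of the same libraries had a median of 0.127% in vehicle and 2.43% in Mn brain.

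The brain count moved with the libraries included. It was 116 and 124 without vehicle 2572 or 2628, and 31, 30, 35, 31, 33 and 30 without Mn 2576, 2577, 2578, 2601, 2602 or 2603. Within animals 2572 to 2578 it was 198 genes (58 higher, 140 lower) and within animals 2600 to 2630 1607 genes (953 higher, 654 lower), so that the excess of higher genes was not kept within 2572 to 2578. With 1 surrogate variable it was 322 (150 higher, 172 lower). In females alone edgeR called 0 genes (339 at an unadjusted p below 0.05), and in males alone 329. Of the 29 genes named by the rule that were called, 24 kept their call in every fit without 1 animal that tested them. For 8 of these that was all 15 fits, and the other 16, Fabp1, Cps1 and Pigr among them, fell below the low-count filter in some and were tested in 8 or 9 of the 15. That filter asks for enough reads in as many libraries as the smaller group holds. A gene read mainly in the doubted Mn libraries can thus go untested when 1 of them is left out. The kept calls of these 16 genes therefore do not test whether they rest on a doubted library. The lower counts without those Mn animals follow in part from the same filter. Besides those above, Mup20 lost its call in 1 of 8 fits (without vehicle 2574, adjusted p = 0.102).

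In liver, where most of the kynurenine pathway is expressed, 51 genes rose and 72 fell among 10536 tested. Kyat3 (ENSMUSG00000040213.14), a kynurenine aminotransferase that makes kynurenic acid, fell from 245 ± 16.4 to 81.1 ± 52.8 CPM (SD, n = 7 and 8; −1.75 ± 0.23, adjusted p = 0.00241) and lay below every vehicle library in 8 of 8 Mn libraries. Tdo2 (ENSMUSG00000028011.17) rose from 1143 ± 256 to 1735 ± 486 CPM (0.56 ± 0.13, adjusted p = 0.0424; above every vehicle library in 6 of 8). Of the 14 pathway genes tested these were the 2 that passed, with 2 up and 1 down when adjusted over the list alone, and the list as a whole was not called (adjusted p = 0.630). The others included Qprt (0.23, adjusted p = 0.113), Afmid (−0.51, adjusted p = 0.175), Kynu (−0.13, adjusted p = 0.590), Haao (0.11, adjusted p = 0.524), Kyat1, the related aminotransferase (0.06, adjusted p = 0.825), and Kmo (0.02, adjusted p = 0.920).

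**Figure D2:**
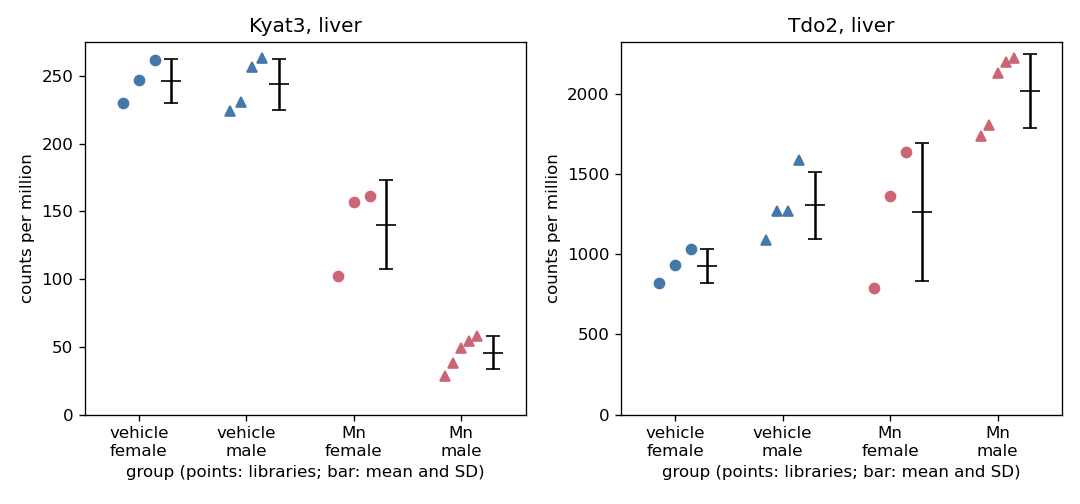
CPM of Kyat3 (left) and Tdo2 (right) in each liver library by treatment and sex (circles, females; triangles, males), with the mean and SD beside the points. Kyat3 averages 246 and 244 CPM in vehicle females and males and 140 and 45.6 CPM in Mn females and males.

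Kyat3 in liver kept its call without any single animal (adjusted p up to 0.0104), and Tdo2 in 4 of 15 such fits (lost without vehicle 2574, 2627, 2628, 2629 or 2630 or Mn 2575, 2576, 2577, 2578, 2601 or 2603, adjusted p up to 0.10). Within animals 2572 to 2578 Kyat3 changed by −1.59 (adjusted p = 0.00298) and within animals 2600 to 2630 by −1.85 (adjusted p = 0.182). The values for Tdo2 were 0.64 (adjusted p = 0.0172) and 0.44 (adjusted p = 0.411). In females alone Kyat3 changed by −0.82 (adjusted p = 0.179) and in males alone by −2.40 (adjusted p = 0.000106), and over all alternatives the adjusted p of Kyat3 ran from 1.9e-18 to 0.182. Without the doubted liver libraries Kyat3 was at −1.31 (adjusted p = 0.00977) and Tdo2 at 0.46 (adjusted p = 0.240, within a range of 0.000121 to 0.614). The libraries left out were all the males of animals 2600 to 2630. The smaller change of Kyat3 therefore cannot be told apart from the lower number of males in that fit.

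Other liver genes changed in both directions. Cfb, complement factor B (ENSMUSG00000090231.11), fell from 400 ± 38.1 to 241 ± 41.6 CPM (−0.73 ± 0.09, adjusted p = 0.00241; below every vehicle library in 8 of 8), and Ppard, a fatty acid receptor, from 19.0 ± 3.79 to 9.47 ± 1.72 CPM (−1.0 ± 0.15, adjusted p = 0.00729). Pdk4, a kinase that holds back pyruvate oxidation, fell from 10.6 ± 2.85 to 2.71 ± 2.34 CPM (−1.95 ± 0.34, adjusted p = 0.0141), and the folding enzyme Pdia3 from 352 ± 95.2 to 226 ± 14.6 CPM (−0.63 ± 0.11, adjusted p = 0.0142). The glycolytic gene Eno1 rose from 141 ± 11.7 to 196 ± 26.3 CPM (0.48 ± 0.09, adjusted p = 0.0178). Maob, a monoamine oxidase, rose by 0.50 ± 0.09 (adjusted p = 0.0141). These genes kept their call without any single animal and belong to the 11 of 35 named and called liver genes that did. Without the doubted libraries Cfb changed by −0.66 and Pdk4 by −2.41, both called, while Pdia3 (−0.61), Eno1 (0.47) and Maob (0.47) were not.

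With the preset correlation 12 of 48 lists were called in liver (4 up, 8 down), and with the estimated correlation 0 (smallest adjusted p = 0.463). The fry test called 2 by direction. Of 99 splits of the animals into groups of the same sizes, the real one included, 34 called as many lists with the preset correlation. Chance is therefore not excluded for the 12 lists. Of the 31 nuclear genes of oxidative phosphorylation, 31 had a positive change (median 0.20), 2 rose and 21 rose when adjusted over the list alone (adjusted p = 0.597 with an estimated correlation). Cox5b rose from 485 ± 89.5 to 634 ± 80.8 CPM (0.37 ± 0.09, adjusted p = 0.0458) and kept its call in 4 of 15 fits without 1 animal (adjusted p up to 0.104). Hepatocyte markers were called up with 3 of 22 risen and 11 when adjusted over the list alone (adjusted p = 0.463 with an estimated correlation). Among these were the amino acid enzymes Hpd (0.44, adjusted p = 0.0472) and Gls2 (0.60, adjusted p = 0.0424). Drug metabolism genes were called up with 4 of 21 risen and 8 adjusted over the list alone (adjusted p = 0.463 with an estimated correlation). Cyp2a5 rose by 1.03 (adjusted p = 0.0451) and Cyp2c54 by 0.82 (adjusted p = 0.0271). Cyp2c54 kept its call in 8 of 15 fits without 1 animal (adjusted p up to 0.0739). Hpd kept it in 3, Gls2 in 4 and Cyp2a5 in 2 of 15 (adjusted p up to 0.109, 0.0968 and 0.104). Gluconeogenesis genes were called up with 1 of 18 risen, Fbp1 (0.35, adjusted p = 0.0472), and 8 adjusted over the list alone (adjusted p = 0.597 with an estimated correlation). Fbp1 kept its call in 3 of 15 fits (adjusted p up to 0.104). Gsta2, a glutathione transferase, rose from 19.6 ± 4.17 to 50.2 ± 24.3 CPM (1.36 ± 0.26, adjusted p = 0.0218). Its call was lost without Mn 2576 or vehicle 2628 or 2629 (adjusted p up to 0.0572).

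Defence and folding lists lay lower in Mn liver. Type I interferon genes were called down, with 29 of 36 negative (median −0.21), 1 fallen and 7 when adjusted over the list alone (adjusted p = 0.694 with an estimated correlation). Isg15 fell from 26.5 ± 7.10 to 14.5 ± 4.34 CPM (−0.87 ± 0.20, adjusted p = 0.0424) and kept its call in 6 of 15 fits without 1 animal (adjusted p up to 0.0968). Inflammatory and acute phase genes were called down with 18 of 20 negative and 4 passing when adjusted over the list alone (adjusted p = 0.694 with an estimated correlation). Of these the serum amyloid gene Saa2 fell from 400 ± 618 to 44.9 ± 29.4 CPM (−2.80 ± 0.60, adjusted p = 0.0385), with vehicle 2627 at 1754 CPM, and it kept its call in 7 of 15 fits without 1 animal (adjusted p up to 0.0744). The unfolded protein response list was called down with 20 of 24 negative, Pdia3 fallen and 2 passing when adjusted over the list alone (adjusted p = 0.694 with an estimated correlation).

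Markers of other tissues also moved in liver. Enterocyte markers were called down with 18 of 19 negative (14 of the 19 higher elsewhere, adjusted p = 0.694 with an estimated correlation). Rbp2, the retinol binding protein of the gut, fell from 261 ± 176 to 32.2 ± 21.3 CPM (−3.02 ± 0.53, adjusted p = 0.0141). It stayed called with the shares as covariates (−3.06, adjusted p = 0.000189), so the estimated shares do not account for its fall. Rbp2 also stayed called without the doubted libraries (−2.79, adjusted p = 0.000678). Those libraries were set by their brain share, so that fit does not test small intestine reads. Paneth cell markers were negative for 7 of 7 (median −1.02) and neuronal markers for 5 of 6 (median −0.60), with all members of both lists higher elsewhere (adjusted p = 0.694 for each with an estimated correlation). The estimated small intestine share of liver libraries had a median of 1.75% in vehicle and 1.25% in Mn, and the brain share 0.758% and 0.330%. Genes higher elsewhere were 27 of the 72 that fell in liver, 5 of the 51 that rose and 4559 of the 10536 tested, so they were not in excess among those that fell.

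Without the 5 doubted liver libraries (vehicle 2627 and 2630, Mn 2601, 2602 and 2603) 6 genes were higher and 45 lower, 18 of them shared with the 123. The split between higher and lower calls moved with the processing. In edgeR, 41.5% of the calls were higher with TMM, 43.4% with RLE and 30.7% with library size alone (46 of 150). With DESeq2, which changes the test as well as the scaling, it was 55.5% (193 of 348). The number of calls was 226, 70, 50, 35, 40 and 41 without vehicle 2572, 2573, 2574, 2627, 2628 or 2629, and 45, 35, 43, 46, 371, 40, 214 and 52 without Mn 2575, 2576, 2577, 2578, 2600, 2601, 2602 or 2603. Within animals 2572 to 2578 it was 198. Within animals 2600 to 2630 it was 4: Bcl6 (−1.88), Hhex (1.67), Syp (−2.37) and AC154178.2 (−1.04), the first 3 outside the rule.

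In small intestine, which takes up dietary metal, 40 genes rose and 14 fell among 11770 tested. Ano6 (ENSMUSG00000064210.8), a lipid scramblase of the cell membrane, rose from 84.1 ± 13.3 to 148 ± 20.1 CPM (SD, n = 7 and 7; 0.81 ± 0.10, adjusted p = 0.00288), and the actin-severing protein Scin from 31.1 ± 6.38 to 51.9 ± 5.74 CPM (0.75 ± 0.10, adjusted p = 0.00469). Prr15 rose by 0.62 ± 0.10 (adjusted p = 0.0125), and all 3 lay above every vehicle library in 7 of 7 Mn libraries. The water and glycerol channel Aqp3 rose from 22.6 ± 5.62 to 50.0 ± 12.6 CPM (1.15 ± 0.18, adjusted p = 0.0125) and the glucose sensor Slc5a4a from 11.6 ± 5.14 to 29.2 ± 8.87 CPM (1.34 ± 0.22, adjusted p = 0.0156). Ly6a, an interferon-responsive surface protein, fell from 51.9 ± 7.27 to 33.4 ± 3.47 CPM (−0.64 ± 0.10, adjusted p = 0.0125; below every vehicle library in 7 of 7). Ifitm3, an antiviral membrane protein, fell from 146 ± 25.3 to 96.7 ± 19.8 CPM (−0.60 ± 0.10, adjusted p = 0.0156). These genes and Abat kept their call without any single animal, 8 of the 23 named genes called. The remaining 15 lost it in some fit, among them Cyp2c29 (1.63, adjusted p up to 0.0566, lost without Mn 2576 or 2578 or vehicle 2629) and Rnf125 (−0.87; up to 0.0566, lost without Mn 2576 or 2578).

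With the preset correlation 15 of 50 lists were called in small intestine (8 up, 7 down), with the estimated correlation 0 (smallest adjusted p = 0.216) and with fry 1 by direction. Of 99 splits of the animals into groups of the same sizes, the real one included, 33 called as many lists with the preset correlation. Chance is therefore not excluded for the 15 lists. All 35 type I interferon genes tested had a negative change (median −0.53), 1 fell and 18 fell when adjusted over the list alone (adjusted p = 0.313 with an estimated correlation). Ifi27l2a fell from 54.3 ± 9.86 to 34.0 ± 9.08 CPM (−0.66 ± 0.14, adjusted p = 0.0362), and kept its call in 5 of 14 fits without 1 animal (adjusted p up to 0.0933). Rsad2 (−1.55, adjusted p = 0.0638), Ifit1 (−1.24, adjusted p = 0.168) and Bst2 (−0.95, adjusted p = 0.0841), all antiviral genes chosen after their values were seen, did not pass. Within animals 2572 to 2578 the list's median was −0.60 and within animals 2600 to 2630 it was −0.39.

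Macrophage markers were called down with 16 of 17 negative (median −0.27), 1 fallen and 8 when adjusted over the list alone (adjusted p = 0.216 with an estimated correlation). The complement gene C1qb fell from 83.1 ± 10.8 to 57.6 ± 9.62 CPM (−0.52 ± 0.11, adjusted p = 0.0374) and kept its call in 6 of 14 fits without 1 animal (adjusted p up to 0.0999). B, plasma and T cell markers were called down with 10 of 14 negative (median −0.26) and 0 fallen (adjusted p = 0.497 with an estimated correlation). Endothelial markers were called down with 12 of 14 negative (adjusted p = 0.437 with an estimated correlation). Pancreatic acinar genes were called down with 7 of 8 negative and 7 passing when adjusted over the list alone (median −6.17, adjusted p = 0.313 with an estimated correlation). Of these Prss2, chosen after its values were seen, was at 276 ± 699 CPM in vehicle and 2.78 ± 5.01 CPM in Mn (adjusted p = 0.0533). Vehicle 2627 carried that mean with 1861 CPM, against 12.2 ± 1.60 CPM in the 6 other vehicle libraries. Without it Prss2 was at −2.17 ± 0.55 (adjusted p = 0.116) and the median of the list at −1.83 (adjusted p = 0.172 with an estimated correlation).

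Genes of the absorbing epithelium lay higher. All 21 enterocyte markers had a positive change (median 0.31), 2 rose and 11 rose when adjusted over the list alone (adjusted p = 0.313 with an estimated correlation). The fructose transporter Slc2a5 rose from 194 ± 40.0 to 306 ± 91.0 CPM (0.66 ± 0.13, adjusted p = 0.0337) and the glucose transporter Slc2a2 from 546 ± 82.4 to 791 ± 136 CPM (0.53 ± 0.11, adjusted p = 0.0399). Each kept its call in 6 of 14 fits without 1 animal (adjusted p up to 0.0933 and 0.129). Markers of position from duodenum to ileum were called up with 14 of 17 positive, 0 risen and 7 when adjusted over the list alone (adjusted p = 0.216 with an estimated correlation). Drug metabolism genes were called up with 13 of 13 positive, Cyp2c29 risen and 4 adjusted over the list alone (adjusted p = 0.313 with an estimated correlation). The estimated brain share of small intestine libraries had a median of 0.701% in vehicle and 0.882% in Mn.

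Metal transport genes were called up as a list in small intestine, with 11 of 16 positive (median 0.09), 0 risen and 6 when adjusted over the list alone (adjusted p = 0.274 with an estimated correlation). The importer of divalent metals Slc11a2 was at 219 ± 62.7 CPM in vehicle and 398 ± 120 CPM in Mn (0.85 ± 0.19, adjusted p = 0.0543), above every vehicle library in 5 of 7. It passed without the doubted libraries (1.01, adjusted p = 0.00994) and in 12 of 31 alternatives in all, with an adjusted p from 1.8e-17 to 0.557. The doubted libraries, all of males, held the highest vehicle value of Slc11a2 (2630, 338 CPM) and its lowest Mn value (2603, 233.7 CPM). They also held its lowest vehicle value (2627, 136 CPM) and a middle Mn value (2602, 409.5 CPM). The larger change without them therefore cannot be told apart from the loss of these values or from the lower number of males. Slc30a10, the Mn exporter, was at 378 ± 53.7 and 500 ± 82.9 CPM (0.41 ± 0.11, adjusted p = 0.117), the Mn importer Slc39a14 changed by 0.30 ± 0.09 (adjusted p = 0.137) and the iron exporter Slc40a1 by 0.36 ± 0.11 (adjusted p = 0.167), without passing. The HIF2-responsive list, which holds iron uptake genes, was called up with 6 of 8 positive, 0 risen and 4 when adjusted over the list alone (adjusted p = 0.216 with an estimated correlation). No kynurenine pathway gene passed among 10 tested (list adjusted p = 0.208). Ido1, which opens the pathway outside the liver, was at 41.3 ± 11 and 46.7 ± 12.9 CPM (adjusted p = 0.777).

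Without the 4 doubted small intestine libraries (vehicle 2627 and 2630, Mn 2602 and 2603) 23 genes were higher and 8 lower, 23 of the 31 shared with the 54. The count was 108, 120, 34, 18 and 17 without vehicle 2572, 2573, 2627, 2628 or 2629, and 86, 12, 30, 12, 25, 31 and 87 without Mn 2575, 2576, 2577, 2578, 2600, 2602 or 2603. Within animals 2572 to 2578 it was 8 and within animals 2600 to 2630 it was 147. In males alone Ano6 was at 0.75 (adjusted p = 0.161, against 2.8e-14 to 0.161 over all alternatives).

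The next comparison asked whether Mn acted differently in males and females. In brain, 8 genes had a higher Mn effect in males and 0 a lower one. The glycine methyltransferase Gnmt (4.81, adjusted p = 0.00276), the carriers Rbp4 (3.15), Apoc1 (3.22) and Apoa2 (4.14), Mat1a (5.87) and Rnase4 (1.95; a mean of 1062 CPM in liver and 27.9 CPM in brain) are far higher in liver than in brain, and the others were Rab4b (2.31) and Pigt (1.14). The male Mn brains were those with liver genes and 2 of the 3 female Mn brains those with small intestine genes. With only genes not higher elsewhere, edgeR called 0 (468 at an unadjusted p below 0.05). The count was 5, 5, 4, 4, 0, 15 and 5 without 2572, 2577, 2600, 2603, 2628, 2629 or 2630, and Gnmt, Rbp4, Apoc1 and Apoa2 lost their call without vehicle 2628 (adjusted p = 0.0506, 0.0595, 0.0595 and 0.125). Rab4b kept its call in 10 of 15 fits, Rnase4 in 6 of 15, Pigt in 3 of 15 and Mat1a in 3 of 8 (adjusted p up to 0.150, 0.125, 0.198 and 0.297).

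In liver the Mn effect was lower in males for 4 genes. Kyat3 went from 246 ± 16.1 to 140 ± 32.8 CPM in females (n = 3 and 3) and from 244 ± 19.0 to 45.6 ± 12.3 CPM in males (n = 4 and 5), a difference of −1.60 ± 0.27 (adjusted p = 0.0364). Ufl1 (−1.14), the retinoic acid hydroxylase Cyp26b1 (−4.08) and Sec23b (−1.51) had the same adjusted p. The count was 0 without 2573, 2574, 2577, 2578, 2600, 2601, 2602, 2603, 2628 or 2629, 1 without 2575 and 9 without 2630. Kyat3 kept its call in 2 of 15 fits, Ufl1 in 3, Cyp26b1 in 4 and Sec23b in 4 (adjusted p up to 0.188, 0.188, 0.188 and 0.197). Without the doubted libraries 19 genes were called. The only males in that fit were vehicle 2573 and 2574 and Mn 2577 and 2578, all of 1 number series. Females of both series remained, so sex cannot be told apart there from the series. In small intestine edgeR called 0 genes (324 at an unadjusted p below 0.05) and DESeq2 0 (149). The smallest p belonged to Hsp90aa1, Steap1 and Sgms2 (adjusted p = 1.0 each).

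Tissues were compared through the tissue by treatment contrasts over 14984 genes. Between liver and small intestine 11 genes differed, 9 with a lower effect in liver. Kyat3 (−1.98), the fatty acid receptor Ppard (−1.08) and the kinase Map3k13 (−1.04) had an adjusted p of 0.0140 each, the metal importer Slc11a2 differed by −1.09 (adjusted p = 0.0346), Ppme1 by −0.93 and Anxa5 by 0.73 (adjusted p = 0.0407). With the animal as a replicate block 7 genes were called. In that fit Kyat3, Ppard, Map3k13, Slc11a2 and Anxa5 passed (adjusted p = 0.0176, 0.0341, 0.00138, 0.0243 and 0.0176), while Rab30, Rtn4, Synpo, Moxd1 and Tacc2 lost their call (adjusted p = 0.0642, 0.0699, 0.0663, 0.0642 and 0.0558). The tissues' own fits gave 9 genes, 0 with a higher and 9 with a lower effect in liver and 5 shared with the 11. The count was 17, 19, 0, 4, 2, 18, 3, 20, 7, 3 and 3 without 2572, 2575, 2576, 2577, 2578, 2600, 2601, 2603, 2627, 2628 or 2629, and Kyat3 lost its call without Mn 2576 or 2578 (adjusted p up to 0.0778) and Ppard and Map3k13 without Mn 2576 (adjusted p = 0.0685). Slc11a2 kept its call in 3 of 15 fits and Ppme1 and Anxa5 in 5 of 15 each (adjusted p up to 0.111, 0.117 and 0.156). The number of genes called was 0 with only genes not higher elsewhere (417 at an unadjusted p below 0.05, edgeR) and 89 without the doubted libraries. The first of these settings drops genes with unlike levels in the tissues compared. Kyat3, Ppard, Map3k13 and Slc11a2 were among those dropped, so that its 0 does not bear on them.

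Brain differed from liver for 865 genes (781 with a higher effect in brain) and from small intestine for 574 (559 higher). Mug1, a liver protease inhibitor, differed by 7.60 and 7.70, and the kynurenine genes Tdo2 by 4.57 and 5.36, Kynu by 3.23 and 3.40 and Haao by 2.38 and 2.15. Kyat3 differed between brain and liver by 2.28. With the animal as a replicate block Haao lost its call between brain and small intestine (adjusted p = 0.0806) and Aadat gained one (adjusted p = 0.000312). Of the 781 and 559 genes, 654 and 515 were higher elsewhere, and the shares of liver and small intestine genes in Mn brain libraries apply here too. Without the doubted libraries 74 and 2 genes were called, the 2 being Bok (1.3) and Ano6 (−1.52), which the rule did not name there. With only genes not higher elsewhere 17 and, by edgeR, 0 (308 at an unadjusted p below 0.05). Mug1, Tdo2, Kynu, Haao and Kyat3 were not tested in that setting. The tissues' own fits gave 171 and 75 genes (170 and 73 shared). On simulated counts the share of false calls of the joint fit was 4.44% to 21.6% for brain against liver, 3.85% to 24.9% for brain against small intestine and 4.05% to 28.9% for liver against small intestine, depending on the dispersion given to filtered genes.

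Genes called in more than 1 tissue were few. Brain and liver shared 3 genes that rose, the liver enzymes Adh1, Fbp1 and Hpd (0.305 expected for independent lists, Fisher's exact test, adjusted p = 0.0207). Their gains in brain were 0.628, 0.726 and 0.820 times those predicted from the other-tissue shares. Brain and small intestine shared Slc2a2 (0.182 expected, exact adjusted p = 0.335) and liver and small intestine shared the fatty acid transporter Cd36 (0.119 expected, exact adjusted p = 0.335). Cd36 rose by 0.85 ± 0.18 in liver (adjusted p = 0.0373) and by 1.02 ± 0.21 in small intestine (adjusted p = 0.0337), and kept its call in 7 of 15 and 6 of 14 fits without 1 animal (adjusted p up to 0.0822 and 0.0933). No gene that fell was shared. At an adjusted p below 0.1 in both tissues liver and small intestine shared 6 lower genes, the interferon genes Bst2 and Rsad2 and the genes Hspa4l, Irf2bp2, Nfil3 and Trp53inp1 (0.983 expected, exact adjusted p = 0.00122). The exact test takes the lists of 2 tissues as independent, which is not met for tissues of the same animals (median correlation of 0.17 between liver and small intestine), so these p-values are not a test of a shared Mn effect.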

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

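The tests that took the gain left over by the predicted reads, that subtracted these reads, that used female-biased liver genes and that used the running sample number were chosen only after the result was seen, as were the fits without the doubted libraries.

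Most genes that rose in Mn brain are abundant in liver or small intestine, and 7 of the 8 Mn brain libraries hold a raised share of the genes of these tissues. If the estimated shares are the cause, each gene's gain in CPM should equal the share multiplied by its level in the source tissue, and 94.4% of the 72 genes (68) lay within 2 times of that prediction, with a median ratio of observed to predicted gain of 0.87; Mup20, Hmgcs1 and Slc7a5 were among those that did not. Raised expression in the brain itself as the whole cause would leave over most of the gain beyond the predicted reads. The predicted reads left over a median of −15.0% (SE 5.47) of the gain of the 72 genes, which argues against that cause. This value restates the ratio of observed to predicted gain, so it is not a separate test. Against liver tissue of the same animal carried along at dissection as the whole cause, the male Mn brains 2577 and 2578 held 1.31% and 2.36% of female-biased liver genes. Vehicle male brains held at most 0.00915%. Xist was at 6.85 and 8.47 CPM in these 2 Mn brains. Their liver shares on markers that were not called were higher, at 3.94% and 4.97%, where a female source alone would give about equal shares. A part of the liver reads in these 2 animals may thus have come from another, female, source, and the source of the rest stays open. For the males 2601, 2602 and 2603 the share of female-biased liver genes was 0.10% to 0.118%, with Xist at 2.27 CPM in 2602 against at most 0.524 CPM in vehicle males, which leaves dissection and later mixing open. In brain libraries the shares also follow the running sample numbers of the deposited files. In complete blocks of 8 numbers, Mn brains 2576 and 2600 (numbers 8 and 16) stand among small intestine libraries and 2577 (24) among liver libraries, and each held reads of that tissue. Mn brain 2575 and the 7 vehicle brains form a block of brain alone and held under 1% of either. This agreement of 11 in 11 brain libraries (3 of them beside another tissue) fits reads or RNA passed between libraries of a block, although the numbers nearly follow treatment. The rule was applied to brain libraries only. The Mn livers 2602, 2603 and 2601 (numbers 30 to 32) stand in a block of liver alone, yet held 1.84%, 1.89% and 2.18% of the brain profile. Passing within a block does not account for those shares. For the brain libraries of 2578 (88) and 2601 to 2603 (94 to 96) the rest of the block was not analysed here. Dissection stays open for 2576 and 2600, and a change that Mn causes in brain below the size of these shares remains untested.

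Kyat3 in liver was lower in Mn mice. Reads of brain and small intestine in the liver libraries are argued against by the low level of Kyat3 there. It averaged 6.4 and 5.9 CPM in these tissues against 158 CPM in liver. Subtracting such reads could therefore hardly move Kyat3, and its log2 change of −1.80 (SE 0.23, edgeR adjusted p = 0.00156) afterwards adds no separate test. Reads passed to neighbouring or related genes are argued against because these genes together gained −0.505% (SE 11.8) of the 165 CPM that Kyat3 lost, with Kyat1 at 6.46 CPM and Gbp2 at −3.04 CPM. A library batch that follows the running sample number carried by the deposited files stays open and cannot be told apart from the treatment, since 0 of the blocks of 8 numbers held liver libraries of both groups. An effect of Mn on Kyat3 in liver is therefore a candidate explanation that stays open beside a batch.

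Libraries far from the rest of their group were found in 36 of the 324 groups of values tested, where chance gives about 1 in 20 (16.2 expected), so a part of them is what chance gives. Among measures of whole libraries, vehicle liver 2630 had a small intestine share of 6.34%, Mn liver 2600 a TMM factor of 1.07, vehicle brain 2628 a mitochondrial share of 8.99% and vehicle brain 2572 a small intestine share of 0.194%.

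In brain, Mn animal 2575 had the lowest level of its group for Fabp1 (3.27 CPM). Vehicle animal 2628 was above its group for Cps1 (2.01 CPM), Ces2a (0.502), Cyp2d26 (0.502), Fgg (5.02), Cyp3a11 (2.51), Fbp1 (3.52) and Hpx (6.03). Vehicle 2627 stood apart for Hnf4a (0.379 CPM), vehicle 2574 for Serpina1e (7.26) and Mup20 (2.99), vehicle 2629 for Slc39a14 (31.8) and Mn 2577 for Serpina1e (296) and Mup20 (96.2). For Ces2a, Cyp2d26 and Hnf4a all other vehicle brains were at 0 CPM, so that these marks rest on very few reads.

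In liver, the animals apart from their group were Mn 2603 for Pdk4 (8.14 CPM), vehicle 2572 for Cyp2c54 (301.4), Mn 2576 for Cd36 (136), vehicle 2627 for Saa2 (1754) and Mt1 (1588), Mn 2602 for Zc3h6 (7.38) and Acmsd (109), Mn 2600 for Ido2 (68.4), Mn 2601 for Slc30a10 (27.8) and vehicle 2573 for Acmsd (59.1). In small intestine they were vehicle 2572 for Slc5a4a (22.3 CPM), Mn 2578 for Slc5a4a (47.1), Cyp2c29 (225) and Slc5a4b (49.5), vehicle 2573 for Rnf125 (79.6), Cyp2c29 (72.7) and Ly6e (478) and Mn 2575 for Slc30a10 (332).

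Effects that differed between the sexes (log2, male minus female) were those of Gnmt (4.81), Rbp4 (3.15), Apoc1 (3.22), Apoa2 (4.14), Rab4b (2.31), Rnase4 (1.95), Pigt (1.14) and Mat1a (5.87) in brain and of Ufl1 (−1.14), Cyp26b1 (−4.08), Sec23b (−1.51) and Kyat3 (−1.60) in liver.

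Effects that differed between brain and liver (log2, brain minus liver) included those of Urah (4.90), Fabp1 (6.26), Mug1 (7.60), Mettl7b (5.69), H2-Q10 (5.24), Haao (2.38), Kynu (3.23), Tdo2 (4.57), Kmo (1.40), Kyat3 (2.28) and Aadat (2.15). Between brain and small intestine they included Urah (4.94), Mettl7b (5.55), Mug1 (7.70), H2-Q10 (5.43), Cps1 (5.39), Haao (2.15), Kynu (3.40) and Tdo2 (5.36). Kmo lost its call between brain and liver without vehicle 2574 or 2627 or Mn 2577 (adjusted p up to 0.0788) and Aadat in 5 of 15 fits without 1 animal (adjusted p up to 0.115), and Haao lost it between brain and small intestine in 7 of 15 such fits (adjusted p up to 0.136). Between liver and small intestine (liver minus small intestine) they were Map3k13 (−1.04), Ppard (−1.08), Kyat3 (−1.98), Rab30 (−1.45), Rtn4 (0.60), Synpo (−0.84), Slc11a2 (−1.09), Ppme1 (−0.93), Moxd1 (−5.16), Tacc2 (−0.85) and Anxa5 (0.73).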

How the results depend on the processing

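The fits without doubted libraries, with shares as covariates, with predicted reads subtracted, with only genes not higher elsewhere and with the tissues' own fits were added after the data were seen. Their smaller counts partly follow from fewer libraries or genes; the cause of the other shifts was not tested. At the depth of these libraries, genes below about 4 CPM rest on fewer than 10 reads.

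The 74 brain genes became 119 with DESeq2, 48 with limma-voom, 542 with no low-count filter, 234 with the stricter filter, 322 with 1 surrogate variable, 198 within animals 2572 to 2578, 1607 within 2600 to 2630, 0 in females alone (339 at an unadjusted p below 0.05, edgeR), 329 in males alone and 33 without the libraries numbered 8, 16 and 24. With only genes not higher elsewhere, with shares as covariates and with subtraction they became 0 (649, 846 and 876 at an unadjusted p below 0.05, edgeR), and without doubted libraries 2. The 123 liver genes became 348 with DESeq2, 519 with no filter, 19 without the sex covariate, 299 with the number series as covariate, 198 and 4 within the series, 7 in females, 39 in males and 51 without doubted libraries. The 54 small intestine genes became 141 with DESeq2, 521 with no filter, 93 with 1 surrogate variable, 90 with the series as covariate, 8 and 147 within the series, 11 in females, 4 in males (Scin, Aqp3, Serpinh1 and, outside the rule, Cyp2c55), 170 with shares as covariates and 31 without doubted libraries. With 1 animal left out these counts ran from 30 to 124, 35 to 371 and 12 to 120, with the animals named in the report.

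For sex differences, the 8 brain genes became 31 with DESeq2, 51 with no filter and 0 with only genes not higher elsewhere (468 at an unadjusted p below 0.05, edgeR); a fit without doubted libraries could not be made there. The 4 liver genes became 24, 159 and, without doubted libraries, 19. The 0 small intestine genes became 43 with no filter and 1 (Hsp90aa1) without doubted libraries. With 1 animal left out the ranges were 0 to 15, 0 to 9 and 0 to 0. The 865 genes of brain against liver became 17 with only genes not higher elsewhere, 74 without doubted libraries and 171 in the tissues' own fits (696 to 1014 with 1 animal left out). The 574 of brain against small intestine became 307 with limma-voom, 0, 2 and 75 (436 to 667). The 11 of liver against small intestine became 7 with the animal as replicate block, 17 with RLE scaling, 3 (Kyat3, Ppard and Map3k13) with only animals that have all 3 tissues, 0 with only genes not higher elsewhere (417 at an unadjusted p below 0.05, edgeR) and 89 without doubted libraries (0 to 20). The replicate block changed no other call among the results named in the report than those given there. Shared lower genes of liver and small intestine went from 0 to 6 at an adjusted p below 0.1.

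Called lists fell from 26 in brain to 12 with the estimated correlation, 15 with fry, 6 with only genes not higher elsewhere and 11 without doubted libraries, from 12 in liver to 0 and 2 (20 with fry's mixed test) and from 15 in small intestine to 0 and 1. Without doubted brain libraries the direction turned for 10 called lists (adjusted p = 0.239 for hepatocyte, 0.387 enterocyte, 0.956 drug metabolism, 0.884 duodenum to ileum, 0.956 HIF2, 0.271 growth hormone, 0.286 inflammatory, 0.0386 MHC class II, 0.608 bile acid and 0.132 choroid plexus genes), and the oxidative phosphorylation list, not called downward over all libraries, was called upward (7.6e-07). With only genes not higher elsewhere it turned for NRF2 (0.899) and smooth muscle (0.962). Among named genes that were called it turned for Apoc3 (−0.23), Fgb (−1.73), Serpina1c (−1.84), Fgg (−5.08), Apoa1 (−0.85), Hpx (−0.70), Mup3 (−1.84), Serpina1e (−1.35) and Hmgcs1 (−0.093) in brain, for Mug1 (−0.16), Mettl7b (−0.12) and Haao (−1.44) against liver and for Mettl7b (−0.28), Cps1 (−0.94) and Haao (−1.69) against small intestine, where 1 Mn brain library was left. Of 1124 other values of 41 named brain genes, 963 kept direction and side of the threshold, as did 1241 of 1703 for 54 liver genes and 985 of 1220 for 40 small intestine genes. Settings in which a gene was not tested are not among these values. In brain, Fabp1 and Cps1 had values in 21 settings each, against 33 for Got2. The number kept in brain thus leaves out fits in which such genes fell below the low-count filter. No called gene turned in liver or small intestine. Genes that were not called changed sign without passing in 27, 36 and 20 of these values (9, 10 and 9 genes).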

Other observations

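The tests on B, plasma and T cell markers, and the genes named in the next 2 paragraphs outside the rule, were chosen only after the result was seen.

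Clock genes were not called as a list in any tissue, and 1 member passed in liver and 1 in small intestine. In liver Nfil3, a repressor of clock output genes, fell from 30.4 ± 9.23 to 18.2 ± 6.32 CPM (SD, n = 7 and 8; −0.80 ± 0.17, adjusted p = 0.0386), and kept its call in 7 of 15 fits without 1 animal (adjusted p up to 0.0841). The clock activator Arntl was at −0.94 (adjusted p = 0.158) and its output gene Dbp at 1.65 (adjusted p = 0.0954; 34.0 and 95.4 CPM), neither of which passed. In small intestine Arntl fell from 50.0 ± 17.8 to 31.4 ± 6.17 CPM (n = 7 and 7; −0.65 ± 0.12, adjusted p = 0.0254), a call lost without Mn 2576, 2578, 2600 or 2602 or vehicle 2629 (adjusted p up to 0.0855), while Nfil3 was at −0.92 (adjusted p = 0.0526) and Dbp at 1.08 (adjusted p = 0.168). The hours at which the tissues were taken are not given in the sources used here.

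Among p53 target and apoptosis genes in liver, 9 of 13 were negative (median −0.26), 0 fell over all genes and 4 when adjusted over the list alone; fry called the list (adjusted p = 0.0246) and camera did not (adjusted p = 0.0531). The glucose-responsive regulator Mlxipl fell in liver from 244 ± 52.4 to 166 ± 32.0 CPM (−0.55 ± 0.11, adjusted p = 0.0218), a call lost without Mn 2576 or vehicle 2627 or 2628 (adjusted p up to 0.0619). In small intestine the collagen chaperone Serpinh1 fell from 69.2 ± 14.2 to 39.5 ± 8.30 CPM (−0.80 ± 0.14, adjusted p = 0.0182), lost without Mn 2576 or 2578 or vehicle 2628 (adjusted p up to 0.0624), and the citrate and succinate transporter Slc13a2 rose from 13.8 ± 5.80 to 40.6 ± 21.6 CPM (1.55 ± 0.31, adjusted p = 0.0337), kept in 7 of 14 such fits (adjusted p up to 0.0933).

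The lower interferon genes in small intestine raise the question of fewer immune cells. The B, plasma and T cell list had a median of −0.26 (SE 0.08) and the MHC class II list a median of −0.12, against −0.53 for the interferon list, which leaves a smaller immune share open as a cause of part of the shift. Against the number series of the animals as the cause, the median was −0.60 within animals 2572 to 2578 (−0.39 within animals 2600 to 2630). A lower interferon response in Mn mice is a candidate explanation that remains open. Chance also remains for the lists as a whole, as the splits of the animals show.

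Splits of the same animals into groups of the same sizes were used to ask whether chance gives as many calls. The real grouping is counted as 1 of the splits in every number below. In brain 3 of 99 splits, the real one and 2 others, gave at least 74 genes, with 2238 the highest of the others, so that chance is excluded at the share of 0.05, but these 2 others called 2238 and 1989 genes and part animals 2600 to 2603 from 2575 to 2578. That points to a structure of the samples, and the counts within the number series were 198 and 1607. For the 26 brain lists only the real grouping was as large (1 of 99, highest other 24). For the 123 liver genes it was again the only one (1 of 99, highest other 3) and for the 54 small intestine genes 1 other split was as large (2 of 99, highest other 109, a split that joins vehicle 2572 and 2574 with Mn 2575 to 2578 and 2600, and so nearly follows the number series, within which the counts were 8 and 147). Chance is thus excluded for the genes called in liver and small intestine and the lists in brain. The splits do not part Mn from a batch that follows the running sample numbers. Vehicle and Mn libraries are numbered 17 to 23 and 25 to 32 in liver and 1 to 7 and 9 to 15 in small intestine. Such a batch would set the real grouping apart in the same way. For the 12 liver lists, 34 of 99 splits called as many (highest other 18), and for the 15 small intestine lists 33 of 99 (highest other 23), so chance is not excluded there. For the sex by treatment term, 2 of 96 splits gave as many as the 8 brain genes (highest other 638, a structure of the samples), 5 of 96 as many as the 4 liver genes (highest other 404) and 98 of 98 as many as the 0 small intestine genes (highest other 200, 324 genes at an unadjusted p below 0.05 in the real comparison by edgeR); chance is excluded for brain alone. For the differences between tissues the real grouping was the only one as large (1 of 60 splits in each case): 865 genes against a highest other of 270 for brain and liver, 574 against 226 for brain and small intestine, and 11 against 1 for liver and small intestine.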
